A study of Homo sapiens with 17 samples.

How the data were processed

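HepG2 cells were grown for 4 days with 0, 2 or 10 µM 5-azacytidine, per the labels. The 17 libraries used were 9 of RNA-seq, 3 per dose, made with a TruSeq Stranded Total RNA kit per the labels, and 8 of ATAC-seq, 3 at 0 µM, 3 at 2 µM and 2 at 10 µM, made with Nextera reagents per the labels. Every value column of the deposited tables was examined, and every library was used.

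The RNA values are raw read counts per gene, made by the authors before deposit; per the submitters' processing notes HISAT2 2.2.1, HTSeq 2.0.4 and DESeq2 1.42.1 were used with the hg38 genome, and the notes give neither the role of each tool nor their order. Whether the counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited count table holds 63187 genes. Of their identifiers 62666 matched a symbol in the gene name table and 521 did not. The ATAC values are raw read counts per peak of 501 bp in a consensus set made by the authors; per the submitters' processing notes DiffBind 3.12.0 was among the tools used. The peak caller is not given in the sources used here. The consensus set holds 63621 peaks, of which 58372 have deposited counts and 5249 do not; the latter were not used. Each peak carries a score deposited by the authors, between 6.425 and 264.83, whose scale is not given in the sources used here, and the score was not used. Peak annotation to genes and gene parts is the authors', as deposited. The deposited table of normalized counts, a signal that the authors made by dividing each library's counts by 1 size factor, holds 21986 genes with at least 30 counts over the 9 libraries. In it the columns named for 10 µM replicates 2 and 3 hold the counts of the other one, as the constant ratio of every gene to the raw counts showed, and it served only for this check. Gene positions are from a RefSeq table of hg38.

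Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, 1 fit per assay over all libraries with a mean per dose, after TMM scaling and the package's own filter on low counts, which left 18999 genes and all 58372 peaks. All 3 pairs of doses were compared in each assay. P-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 was called a rise or a fall. Every adjusted p of a gene or peak in the results is from this test unless another is named. Fold changes use edgeR's prior count of 0.125, and the SE is the absolute log2 change over the square root of F. Where a gene had 0 counts in a group, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts is given with its 95% counting interval. For peaks with so few counts in a group the counts are given instead.

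A total of 24 gene lists was written from general knowledge before the data were examined, together with the tests, the alternatives and the rule for naming genes. They cover DNA methylation machinery, nucleoside uptake and pyrimidine metabolism, cancer-testis and germline genes, interferon-stimulated genes, MHC class I antigen presentation, p53 targets, S-phase genes, G2/M genes, secreted liver proteins and liver transcription factors, oncofetal and imprinted genes, the BCL2 family, sulfide and sulfur amino acid metabolism, the integrated stress response, the unfolded protein response, cholesterol synthesis, NF-kappaB and inflammatory genes, genes often methylated in liver cancer, metallothioneins, mitochondrially encoded genes, ribosomal proteins, and markers of leukocytes, of fibroblasts and stellate cells, of cholangiocytes and other epithelia, and of endothelium. Lists were tested with camera of limma 3.58.1, two-sided, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and fry were the alternatives.

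Genes were named by this rule. First came BCL2A1, SQOR, DNMT1, DNMT3A, DNMT3B and UHRF1. In each RNA comparison the 10 protein-coding genes with the largest positive and the 10 with the largest negative log2 change were taken among those past the threshold with at least 1 CPM in the higher group and no overlap between the libraries of both groups, an overlap that chance avoids in 10% of genes. In each list and comparison up to 4 members with the smallest adjusted p were taken. Peaks were named if they overlapped BCL2A1 or SQOR or lay within 5000 bp, or were among the 5 largest changes per direction and comparison under the same conditions. Up to 10 genes called in RNA with a promoter peak called in the same direction were added by RNA adjusted p. The text gives a part of these, with a preference for calls that no single library ended, and the names outside the rule are said to be so.

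Genes silent in control were those with a mean under 0.1 CPM at 0 µM. The overlap of doses was set beside independent lists and beside 20 simulations of unchanged groups and their shared controls, drawn around the control means. For promoters, genes with at least 1 peak within 1000 bp of an annotated transcription start were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 4 tests.

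Same-numbered RNA libraries of 0 and 2 µM deviated together from their group means (r = 0.194, 0.264 and 0.283 across genes for replicates 1 to 3, each above 0.1 and above any differently numbered library), so these numbers were taken to pair them. This rests on the data, since the labels name no shared day or batch. Deviations from a mean of 3 libraries cancel out, so the 3 correlations are not separate evidence of pairing. Where the replicate number as a block changed a call of this comparison, the blocked value stands beside it.

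The alternatives were DESeq2's size factors (RLE), total counts as the only scaling, the DESeq2 1.42.0 Wald test, no filter beyond 1 count, only the compared groups in the fit, the replicate number as a block, a further threshold of 1 on the absolute log2 change, each library left out in turn, a peak set of at least 1 CPM, other definitions of silent genes, and promoters within 3000 bp or overlapping the start itself. Added after the data were seen were leaving out both RNA libraries numbered 3 of 0 and 2 µM, a block over those doses alone, a block with the numbers of 10 µM replicates 2 and 3 exchanged, leaving out each library for the silent genes, overlap and promoter results, lists and silent genes without a filter, with the germline list also set against silent genes alone, and the overlap of doses with separate controls, 1 library for one dose and the other 2 for the other.

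The method was tested on simulated counts with the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For RNA it recovered 21% and 62% of them at 2 against 0 µM, 15% and 65% at 10 against 0 µM, and 17% and 61% at 10 against 2 µM, with 8, 5 and 8 false calls among 18999 genes. For ATAC it recovered 78% and 100%, 77% and 99%, and 71% and 100%, with 12, 11 and 9 false calls among 58372 peaks. The RNA false calls stand beside 21 and 62, 15 and 65, and 17 and 61 recovered genes, a share above 0.05 in this single draw. The real RNA data had 4.28% of genes called at 2 and 48.1% at 10 against 0 µM. Fewer changed genes, as simulated here, make the adjusted p stricter, so these recoveries do not measure what the real comparisons missed. Camera gave a list of 30 genes raised 1.5-fold a p of 3.58e-17 in the 10 against 0 µM layout of 18999 genes, and none of 20 unchanged lists a p under 0.05. The simulated genes varied independently, so this cannot show how the preset correlation does in lists whose members move together. For S-phase genes at 10 against 0 µM, for example, the estimated correlation was 0.795. RNA depth lay between 35553052 and 46430168 counts and ATAC depth between 2896671 and 7864321 reads in peaks. Motifs, CpG content and repeats were not analysed here, since no genome sequence was at hand.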

Results

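HepG2 cells, a human liver carcinoma line, were profiled after 4 days with 0, 2 or 10 µM 5-azacytidine. This cytidine analogue is built into nucleic acids and traps DNA methyltransferases. RNA was measured by RNA-seq in 9 libraries, 3 per dose, and open chromatin by ATAC-seq, in which a transposase cuts accessible DNA, in 8 libraries (3 at 0 µM, 3 at 2 µM and 2 at 10 µM). Total RNA counts for replicates 1 to 3 were 35553052, 41174097 and 44220965 at 0 µM, 40104508, 41067431 and 44880960 at 2 µM, and 39904820, 46430168 and 45702708 at 10 µM. ATAC reads counted in 58372 peaks of 501 bp were 4054573, 7333355 and 5227211 at 0 µM, 2907068, 2896671 and 7042886 at 2 µM, and 7864321 and 4699599 at 10 µM. Levels are in CPM, the deposited counts scaled to a common library size, as mean ± SD (n = 3 per dose, n = 2 for ATAC at 10 µM). Changes are log2 ratios with the SE of the edgeR fit, and "rose" or "fell" is written only where the adjusted p was under 0.05. The labels call the libraries biological replicates without saying whether each came from a separate culture, so every p measures only the spread between these libraries. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers.

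The 10 µM libraries stood apart in both assays. The first principal component of the RNA held 63.5% of the variance and that of the ATAC data 77.0%. ATAC libraries at 10 µM correlated with those at 0 µM with a median r of 0.338 across peaks, against 0.954 among the 0 µM libraries and 0.942 between the 10 µM pair. RNA libraries at 2 µM correlated with those at 0 µM with a median r of 0.955 across genes, against 0.966 among the 0 µM libraries. Replicates numbered 3 at 0 and 2 µM carried more mitochondrial mRNA than the other 7 RNA libraries (0.271% and 0.232% of counts against 0.0664% to 0.143%). The same pair carried less of the cytoplasmic RNA 7SL (1.02% and 1.08% of counts, against 1.46% to 4.09% in the other 0 and 2 µM libraries).

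The series is titled for BCL2A1 and SQOR, and the first question was whether the drug changed their RNA and chromatin. BCL2A1 encodes the anti-apoptotic protein BFL-1, and SQOR the mitochondrial enzyme that oxidises hydrogen sulfide. Both genes had more RNA at both doses than without drug, and both had a promoter peak that opened further with each dose. BCL2A1 (ENSG00000140379.9, hg38 chr15:79960892-79971196) stood at 1.01 ± 0.361 CPM at 0 µM, 7.21 ± 4.56 CPM at 2 µM and 10.7 ± 3.52 CPM at 10 µM. Its log2 change was 2.82 (SE 0.542, adjusted p = 0.0122) at 2 µM and 3.39 (SE 0.551, adjusted p = 0.000268) at 10 µM. The 2 µM call was lost without 2 µM replicate 1 (adjusted p = 0.0528), without 2 µM replicate 2 (0.0607), and in a fit of 0 and 2 µM with the replicate number as a block (log2 2.61, adjusted p = 0.0532). SQOR (ENSG00000137767.14, chr15:45631148-45691281) stood at 18.6 ± 0.688, 45.3 ± 12.9 and 37.8 ± 3.59 CPM. It rose by a log2 of 1.28 (SE 0.223, adjusted p = 0.00698) at 2 µM and 1.02 (SE 0.222, adjusted p = 0.00209) at 10 µM. Neither gene passed between the 2 drug doses (adjusted p = 0.386 for BCL2A1 and 0.377 for SQOR). With replicates 3 of 0 and 2 µM both left out, SQOR was lower at 10 than at 2 µM (log2 -0.50, adjusted p = 0.0328).

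**Figure D1:**
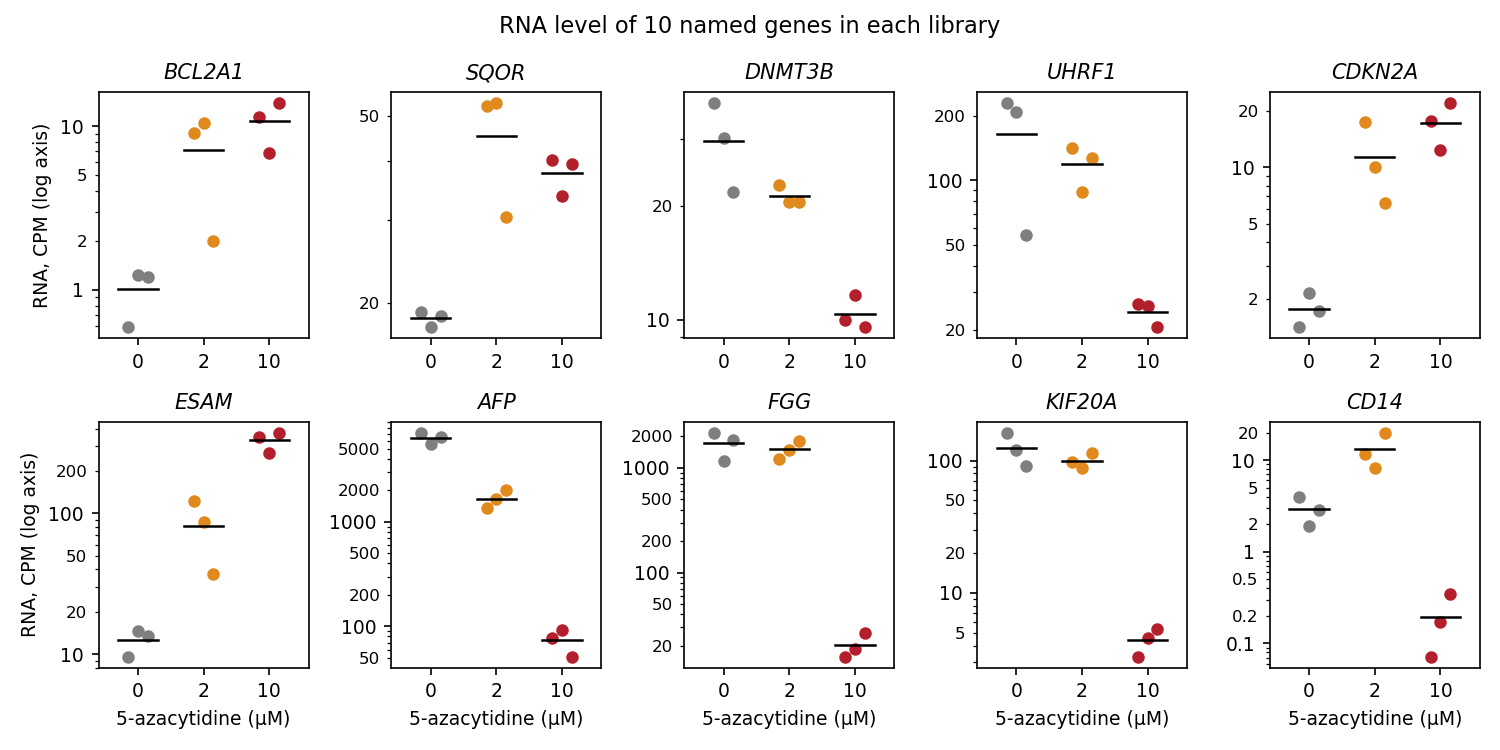
RNA of 10 genes (vertical axis, CPM, log scale) against the dose of 5-azacytidine (horizontal axis, µM). Points are single libraries and each short line marks the mean of 3 at a dose. BCL2A1 and SQOR stood higher at both drug doses than without drug, while AFP went from 6398 CPM without drug to 1669 CPM at 2 µM and 73.4 CPM at 10 µM.

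The BCL2A1 promoter peak (chr15:79970891-79971391) held 2.03 ± 0.349 CPM at 0 µM, 7.41 ± 1.35 CPM at 2 µM and 22.8 ± 3.08 CPM at 10 µM. It rose by a log2 of 1.85 (SE 0.292, adjusted p = 2.08e-05) at 2 µM, 3.50 (SE 0.253, adjusted p = 2.94e-13) at 10 µM, and 1.65 (SE 0.217, adjusted p = 1.24e-07) from 2 to 10 µM. A peak in intron 2 of BCL2A1 (chr15:79966175-79966675) rose at 10 µM by 1.17 (SE 0.207, adjusted p = 1.05e-05) and did not pass at 2 µM (adjusted p = 0.465). The SQOR promoter peak (chr15:45631261-45631761) held 3.66 ± 1.62, 10.6 ± 1.28 and 27.3 ± 0.464 CPM, with rises of 1.60 (SE 0.265, adjusted p = 3.88e-05) at 2 µM, 2.99 (SE 0.24, adjusted p = 2.5e-12) at 10 µM, and 1.39 (SE 0.213, adjusted p = 1.63e-06) between those doses. The next peak downstream (chr15:45634463-45634963), which the deposited annotation also calls promoter, did not pass at 10 µM (log2 -0.23, adjusted p = 0.188). In an intron of SQOR, the peak at chr15:45640587-45641087 rose at 10 µM by 2.23 (SE 0.233, adjusted p = 5.84e-10).

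**Figure D2:**
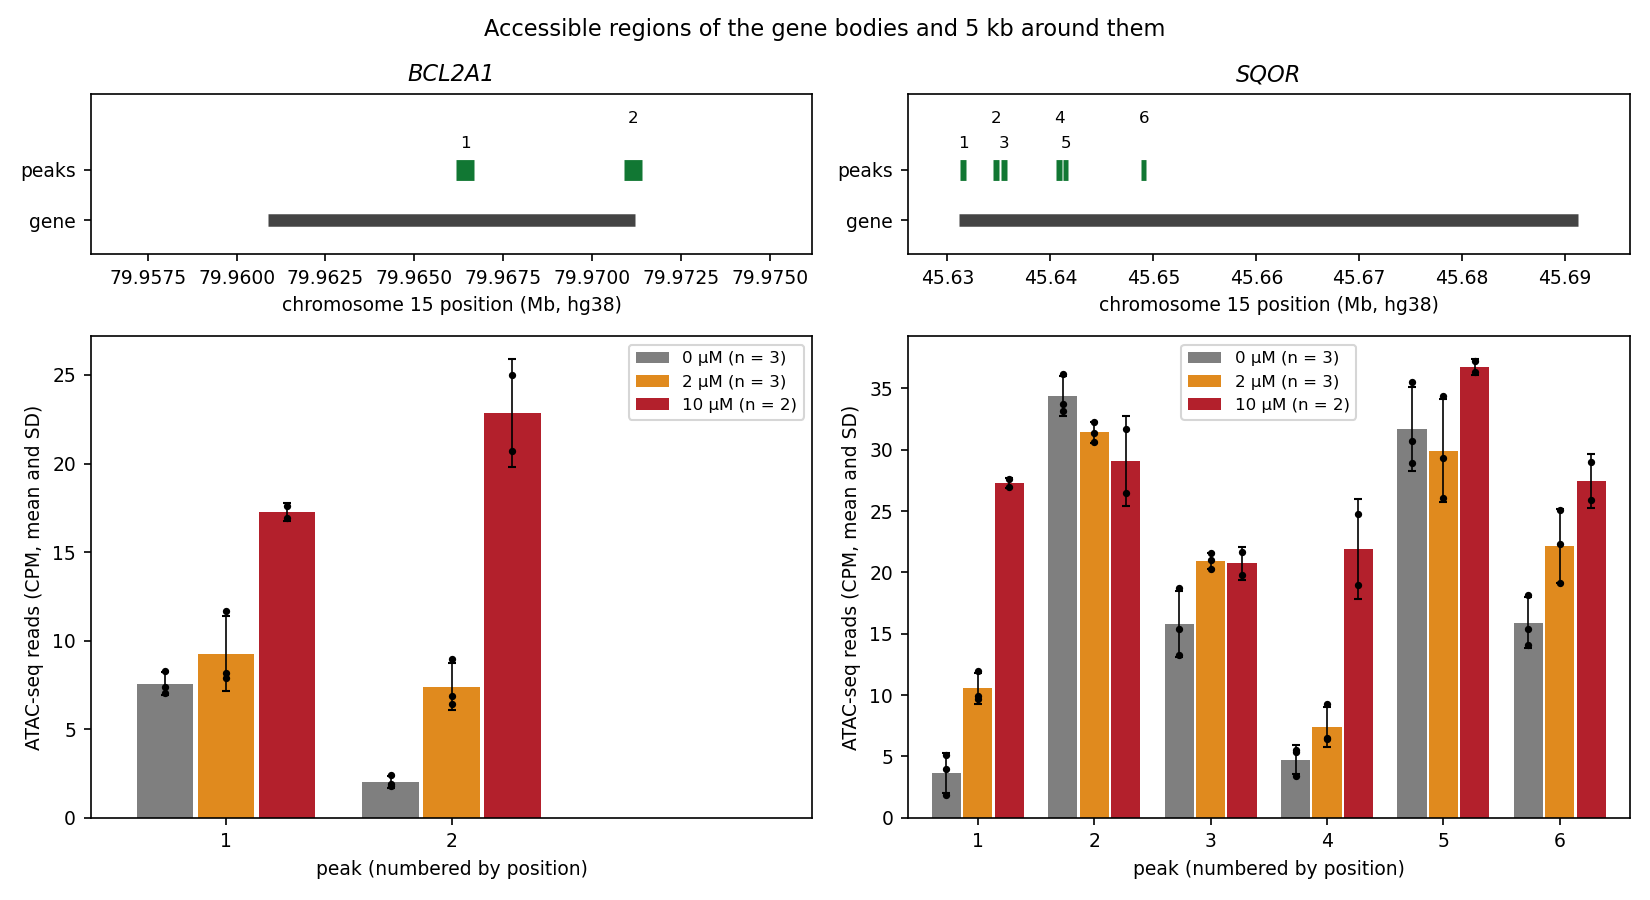
Maps of BCL2A1 and SQOR along chromosome 15 (horizontal axis, hg38 position) with the counted ATAC peaks, and the level of each peak (vertical axis, CPM). Bars, coloured by dose, are means with the SD, and black points are libraries. The promoter peaks of both genes stood at 22.8 and 27.3 CPM at 10 µM, above 2.03 and 3.66 CPM without drug.

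The comparison of 2 with 0 µM asks what a dose leaving the RNA profile close to control changed. Some germline genes that control cells left all but silent came on, and so did some imprinted RNAs. The cell-cycle inhibitors at the CDKN2A locus, already expressed in control, rose. Genes of cholesterol synthesis, mitosis, protein folding and liver secretion were lower as groups, by smaller amounts per gene, in calls of which none held with an estimated correlation between genes (adjusted p = 0.488 to 0.631). Of 18999 genes tested, 611 rose and 202 fell. The 611 became 320, 386 and 947 without 0 µM replicates 1, 2 and 3, and 264 and 244 without 2 µM replicates 1 and 2. The 202 became 96 and 462 without 0 µM replicates 1 and 3, 29, 32 and 432 without 2 µM replicates 1, 2 and 3, and 113 and 108 without 10 µM replicates 1 and 3. With the replicate number as a block over the 0 and 2 µM libraries, 399 rose and 314 fell. Scaling by total counts alone shifted the median of all genes by 0.148 in log2 and gave 904 and 94, so that 90.6% rather than 75.2% of calls were rises, and DESeq2 gave 982 and 539, of which 64.6% were rises.

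The largest rises at 2 µM began from few or no reads. ATL3, an atlastin that shapes the endoplasmic reticulum (ENSG00000184743.13, chr11:63624087-63671974), had 0 counts at 0 µM and 11.9 ± 4.68 CPM at 2 µM, at least 428-fold higher over a floor of 3 counts in the 0 µM group (adjusted p = 2.36e-05). TDRD9, a helicase that silences transposons in germ cells (ENSG00000156414.20, chr14:103928456-104052667), went from 0 counts to 4.94 ± 2.13 CPM, at least 178-fold higher (adjusted p = 7.35e-05). PXMP4, a peroxisomal membrane protein (ENSG00000101417.12, chr20:33702758-33720310), went from 0.0342 to 7.34 ± 1.83 CPM, a log2 change of 7.56 (SE 0.571, adjusted p = 2.36e-05), and stood at 0.0784 CPM at 10 µM. H19 (ENSG00000130600.22, chr11:1995176-2001266) and MEG3 (ENSG00000214548.18, chr14:100826108-100861026) are imprinted non-coding RNAs. H19 rose from 0.0342 ± 0.0391 to 17.2 ± 3.33 CPM, a log2 change of 8.78 (SE 0.608, adjusted p = 1.91e-05). MEG3 reached 8.49 ± 1.21 CPM, a count ratio of 941 (95% counting interval 168 to 37200, adjusted p = 0.000347). CDKN2A, which encodes the inhibitors p16 and ARF (ENSG00000147889.18, chr9:21967752-21995324), rose from 1.75 ± 0.366 to 11.4 ± 5.65 CPM (log2 2.69, SE 0.374, adjusted p = 0.00202).

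Among the falls at 2 µM, AFP, the fetal liver counterpart of albumin (ENSG00000081051.8, chr4:73436221-73456174), went from 6398 ± 789 to 1669 ± 323 CPM (log2 -1.94, SE 0.238, adjusted p = 0.000778). DKK1, a secreted Wnt inhibitor (ENSG00000107984.10, chr10:52314281-52317657), fell from 165 ± 45 to 38.5 ± 9.75 CPM (log2 -2.10, SE 0.348, adjusted p = 0.00506). The aldo-keto reductases AKR1C1 and AKR1C2, whose near-identical sequences leave their shares of reads uncertain, had log2 changes of -2.34 and -2.44 (adjusted p = 7.96e-05 and 0.00211). HEPACAM, an adhesion protein of liver cells, had a log2 change of -2.39 (SE 0.381, adjusted p = 0.00409).

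Of 24 gene lists fixed before the data were examined, camera called the cancer-testis and germline list higher at 2 µM (20 measured, median log2 2.23, adjusted p = 1.72e-18). With an estimated correlation between genes its adjusted p was 0.0871. In that list 9 genes rose and 11 did not pass, and 14 rose adjusted over the list alone. The count filter left out 42 of its 62 genes, and a gene this low in control mostly passes the filter where a drug group is high, which favours rises. Without the filter, in an alternative added after the data were seen, 51 of the 62 had a count, 13 rose and none fell (adjusted p = 1.02e-14). Set only against 733 other silent genes, which passed the same filter, the 9 silent members had a median log2 of 5.43 against 2.40 (camera p = 0.0118, or 0.223 with an estimated correlation). TDRD12, a piRNA pathway gene, rose from 0.122 ± 0.087 to 6.07 ± 0.954 CPM (log2 5.56, SE 0.493, adjusted p = 7.35e-05), and SYCP3, a protein of paired meiotic chromosomes, by 5.01 (SE 0.834, adjusted p = 0.00525). The cholesterol synthesis list of 24 was lower (median -0.95, adjusted p = 2.08e-11; adjusted p = 0.488 with an estimated correlation). None of its genes passed in edgeR over all genes, 16 fell adjusted over the list alone, 19 were lower at an unadjusted p under 0.05, and DESeq2 called 8 lower. The G2/M list of 39 was lower (median -0.439, adjusted p = 2.16e-09; adjusted p = 0.614 with an estimated correlation). Of its genes 2 fell, or 7 adjusted over the list alone, namely CKS2, a cyclin-dependent kinase subunit (adjusted p = 0.0424), and PTTG1, the securin that restrains sister chromatid separation (adjusted p = 0.0269). Both calls were lost without any 1 of the libraries other than 0 µM replicate 3, with an adjusted p of up to 0.17 for CKS2 (without 2 µM replicate 1) and up to 0.114 for PTTG1 (without 2 µM replicate 1) or with the block over 0 and 2 µM (0.0534 and 0.0502), and under total counts the list's median was -0.282 with no member past the threshold.

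The list of secreted liver proteins and liver transcription factors was lower at 2 µM (47 measured, median -0.406, adjusted p = 0.000138; adjusted p = 0.631 with an estimated correlation). Of these 4 fell, or 5 adjusted over the list alone: ALB, APOB, TTR and F5, which encode albumin, the apolipoprotein of low-density lipoprotein, transthyretin and a clotting factor. The log2 changes of ALB and APOB were -1.39 and -1.16 (adjusted p = 0.0247 and 0.0269). All 4 calls were lost without 0 µM replicate 1 (adjusted p = 0.0546 to 0.0612), without 2 µM replicate 1 (0.107 to 0.131) and without 2 µM replicate 2 (0.106 to 0.126). The unfolded protein response list of 20 was lower (median -0.337, adjusted p = 0.000146; adjusted p = 0.488 with an estimated correlation). HSPA5, PDIA4, PDIA6 and CALR, which fold proteins in the endoplasmic reticulum, fell, and 6 fell adjusted over the list alone. HSPA5 had a log2 change of -0.93 (adjusted p = 0.0234). All 4 were lost without 0 µM replicate 1 (adjusted p = 0.0901 to 0.145), without 2 µM replicate 1 (0.128 to 0.206) and without 2 µM replicate 2 (0.118 to 0.179), and with the block over 0 and 2 µM (0.0512 to 0.0892). PDIA4, PDIA6 and CALR were also lost without 0 µM replicate 2 (0.0531 to 0.0798) or any 10 µM library (0.055 to 0.0939), and under total counts no member of the list passed.

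Another 5 list calls at 2 µM rested on single libraries. The integrated stress response list was higher (29 measured, median 0.212, 2 rose, 3 adjusted over the list alone, adjusted p = 0.0106; adjusted p = 0.65 with an estimated correlation), and lost without 0 µM replicate 1 (0.118), 0 µM replicate 2 (0.0683) or 2 µM replicate 1 (0.158). In it ATF5, a transcription factor of the amino acid stress response, rose by a log2 of 2.70 (SE 0.318, adjusted p = 0.000579). The endothelial marker list was higher (7 measured, median 1.28, 2 rose, 4 adjusted over the list alone, adjusted p = 0.00169; adjusted p = 0.488 with an estimated correlation), and lost without 0 µM replicate 1 (0.0681). The junction protein ESAM, which rose by a log2 of 2.70 (SE 0.356, adjusted p = 0.00141) to 81.8 ± 42.5 CPM, belongs to it. Interferon-stimulated genes were higher (38 measured, median 0.156, 3 rose and 1 fell, 6 and 2 adjusted over the list alone, adjusted p = 0.047; adjusted p = 0.488 with an estimated correlation). That call was lost without 0 µM replicate 2 (0.111), 2 µM replicate 1 (0.0573), 2 µM replicate 3 (0.202) or a 10 µM library (0.0541, 0.0547 and 0.0549 for replicates 1 to 3), and with the replicate number as a block (0.0748 over all doses, 0.0869 over 0 and 2 µM). Metallothioneins, zinc-binding proteins whose similar copies share reads, were lower (7 measured, median -1.12, adjusted p = 0.0214; adjusted p = 0.631 with an estimated correlation). None of them passed in edgeR over all genes, 2 fell adjusted over the list alone, 4 were lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. The metallothionein call was lost without 0 µM replicate 2 (0.35), 2 µM replicate 1 (0.0573) or 2 µM replicate 2 (0.0619), and with the block over 0 and 2 µM (0.0527). Ribosomal proteins were lower (70 measured, median -0.113, which under total counts flips to 0.0439; adjusted p = 0.0421 and, with an estimated correlation, 0.835). In that list no gene passed in edgeR, adjusted over the list alone or over all genes, 1 was lower at an unadjusted p under 0.05, and DESeq2 called none. The ribosomal call was lost without 0 µM replicate 1 (0.733), 2 µM replicate 2 (0.0514), 2 µM replicate 3 (0.501) or a 10 µM library (0.0582, 0.0547 and 0.0549 for replicates 1 to 3), and with the block over 0 and 2 µM (0.0915).

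The other 14 lists did not pass at 2 µM. Of 25 oncofetal and imprinted genes 5 rose and 2 fell, and 5 and 4 adjusted over the list alone (adjusted p = 0.916, with a median of -0.245, a mean of 0.799 and a test leaning up). Among 26 sulfide and sulfur amino acid genes SQOR rose and 25 did not pass, with the same count adjusted over the list alone (adjusted p = 0.955; median -0.0817, mean 0.0138, test up). Of 33 genes often methylated in liver cancer 4 rose and 1 fell, and 8 and 4 adjusted over the list alone (adjusted p = 0.402; median -0.0664, mean 0.136, test up). In it CDKN2B, the neighbour of CDKN2A, rose by a log2 of 1.70 (SE 0.309, adjusted p = 0.00888). The BCL2 family list of 18, with BCL2A1, had 3 that rose, also adjusted over the list alone (adjusted p = 0.135, or 0.00745 without 2 µM replicate 3 and 0.0181 without the count filter). Of 36 p53 targets 2 rose and 1 fell, and 6 and 1 adjusted over the list alone (adjusted p = 0.0548). The p53 list was called higher without 0 µM replicate 2 (0.0417), 0 µM replicate 3 (0.0356) or 2 µM replicate 3 (0.0137), and with the replicate number as a block (0.0418 over all doses, 0.0345 over 0 and 2 µM) or without the count filter (0.00861). Of 20 NF-kappaB and inflammatory genes 3 rose, and 4 rose and 3 fell adjusted over the list alone (adjusted p = 0.609, or 0.0302 without 0 µM replicate 3). Among 28 nucleoside and pyrimidine genes 1 rose, or 2 adjusted over the list alone (adjusted p = 0.376, or 0.0302 without 0 µM replicate 3). Among 19 genes of MHC class I presentation CALR fell, over the list alone too (adjusted p = 0.237). None of 40 S-phase genes passed in edgeR, adjusted over the list alone or over all genes, with 3 lower at an unadjusted p under 0.05 and none in DESeq2 (adjusted p = 0.108, or 3.52e-13 without 0 µM replicate 3). Of 12 mitochondrially encoded genes none passed in edgeR, at an unadjusted p under 0.05 or in DESeq2 (adjusted p = 0.237, or 0.00257 without 0 µM replicate 1 and 0.00946 without 2 µM replicate 3). Leukocyte markers had 2 that rose and 1 that fell (2 and 2 adjusted over the list alone; adjusted p = 0.609), fibroblast and stellate cell markers 1 that fell (2 rose and 2 fell adjusted over the list alone; 0.833), and cholangiocyte markers 1 that rose (1 and 1 adjusted over the list alone; 0.288). Of 46 list members named by the rule and called at 2 µM, 27 lost the call without at least 1 library.

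The comparison of 10 with 0 µM asks what the higher dose did. Most listed genes of liver cells, mitosis, DNA replication, cholesterol synthesis, protein folding and ribosomes fell, and 16 of 20 measured germline genes rose. At 2 µM 9 of the 20 rose, or 14 adjusted over the list alone. Between the drug doses 4 rose and 4 fell, and the germline list did not pass (camera adjusted p = 0.483). The count filter, which favours rises, left out 42 of the 62 listed germline genes. Without it 21 of 51 rose and 2 fell at 10 against 0 µM. With an estimated correlation between genes 0 lists were called. Of 18999 genes 4371 rose and 4767 fell, 48.1% of those tested. Total-count scaling shifted the median of all genes by 0.237 and gave 5788 and 3747, so that 60.7% rather than 47.8% of calls were rises. Every list called at 10 µM, except the fibroblast list, kept its call without each single library. The list medians below did not move when genes at 0 counts in a group were set at their bound.

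Among 47 genes of secreted liver proteins and liver transcription factors 45 fell, with the same count adjusted over the list alone (median -4.31, adjusted p = 5.18e-42; adjusted p = 0.2 with an estimated correlation). FGG, a chain of fibrinogen (ENSG00000171557.17, chr4:154604136-154612656), fell from 1736 ± 514 to 20.2 ± 5.54 CPM (log2 -6.43, SE 0.33, adjusted p = 1.01e-07). APOH, a plasma phospholipid-binding protein, fell from 1749 to 31.7 CPM (log2 -5.79, SE 0.305), and the bile acid receptor NR1H4 had a log2 change of -6.38. AFP fell to 73.4 ± 20.6 CPM (log2 -6.45, SE 0.291, adjusted p = 6.33e-08). SLC6A14, an amino acid transporter, fell from 129 ± 40.3 to 0.122 CPM (log2 -10.04, SE 0.623, adjusted p = 2.11e-07). CA9, a carbonic anhydrase induced by low oxygen, went from 36.2 ± 33.2 CPM to 0 counts, at least 1770-fold lower.

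All 39 G2/M genes fell, also adjusted over the list alone (median -3.81, adjusted p = 3.67e-55; adjusted p = 0.184 with an estimated correlation). KIF20A, a motor of the dividing cell's midzone (ENSG00000112984.12, chr5:138179112-138187723), fell to 4.40 CPM from 125 ± 35.9 CPM (log2 -4.82, SE 0.278, adjusted p = 1.36e-07), and the centromere histone CENPA had a log2 change of -4.94. Of 40 S-phase genes 35 fell, also adjusted over the list alone, among them the replication licensing factor CDT1 (log2 -3.10) (median -1.86, adjusted p = 3.38e-11; adjusted p = 0.427 with an estimated correlation). Among 28 nucleoside and pyrimidine genes 13 fell and 1 rose. TYMS and TK1, which make thymidine monophosphate, fell (log2 -2.63 and -3.83), and UPP1, which splits uridine, rose (2.94). Adjusted over the list alone 13 fell and 2 rose (adjusted p = 0.0102; adjusted p = 0.288 with an estimated correlation). Of 70 ribosomal protein genes 65 fell, or 67 adjusted over the list alone (median -0.916, or -0.665 with 50 falls under total counts; adjusted p = 4.92e-10 and, with an estimated correlation, 0.427). Of 24 cholesterol genes 21 fell, or 23 adjusted over the list alone (adjusted p = 1.06e-09; adjusted p = 0.288 with an estimated correlation). Of 20 unfolded protein response genes 15 fell, or 16 adjusted over the list alone, HSP90B1 with a log2 change of -3.21 (adjusted p = 5.56e-09; adjusted p = 0.2 with an estimated correlation). Of 19 genes of MHC class I presentation 13 fell, also adjusted over the list alone, such as the proteasome activator PSME1 (log2 -1.66) (adjusted p = 6.81e-05; adjusted p = 0.278 with an estimated correlation).

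In the cancer-testis list 16 of 20 rose at 10 µM and 1 fell, or 16 and 2 adjusted over the list alone (median 3.18, adjusted p = 5.25e-06; adjusted p = 0.2 with an estimated correlation). Without the count filter 21 of 51 rose and 2 fell (adjusted p = 3.42e-06), and against 733 other silent genes the 9 silent members did not pass (median log2 6.67 against 3.41, camera p = 0.0687, or 0.343 with an estimated correlation). With the filter the gene that fell was PIWIL2, singled out after its value was seen. TDRD9 stood at 3.18 ± 0.582 CPM, at least 116-fold over control, and TEX14 of germ cell bridges rose by 4.09. Among 25 oncofetal and imprinted genes 13 fell and 5 rose, or 14 and 6 adjusted over the list alone (median -0.649, adjusted p = 0.00691; adjusted p = 0.295 with an estimated correlation). GRB10, an imprinted adaptor of insulin signalling, rose from 30.5 to 603 CPM (log2 4.30, SE 0.413, adjusted p = 4.31e-06), and DLK1, a secreted regulator of growth, fell by 3.66. Cholangiocyte and other epithelial markers had 7 that fell and 2 that rose of 11, also adjusted over the list alone (adjusted p = 0.0167; adjusted p = 0.214 with an estimated correlation), the adhesion protein EPCAM with a log2 change of -1.29. Fibroblast and stellate cell markers had 6 that fell and 2 that rose of 9, also adjusted over the list alone (adjusted p = 0.0258; adjusted p = 0.2 with an estimated correlation). Their list call was lost without 0 µM replicates 1 (0.0677) or 3 (0.149), 2 µM replicates 1 (0.0745), 2 (0.0624) or 3 (0.0757), or 10 µM replicate 2 (0.118), and without the count filter (0.0519). FN1, the matrix protein fibronectin, fell from 9438 to 1655 CPM at 10 µM, alongside the liver genes.

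**Figure D3:**
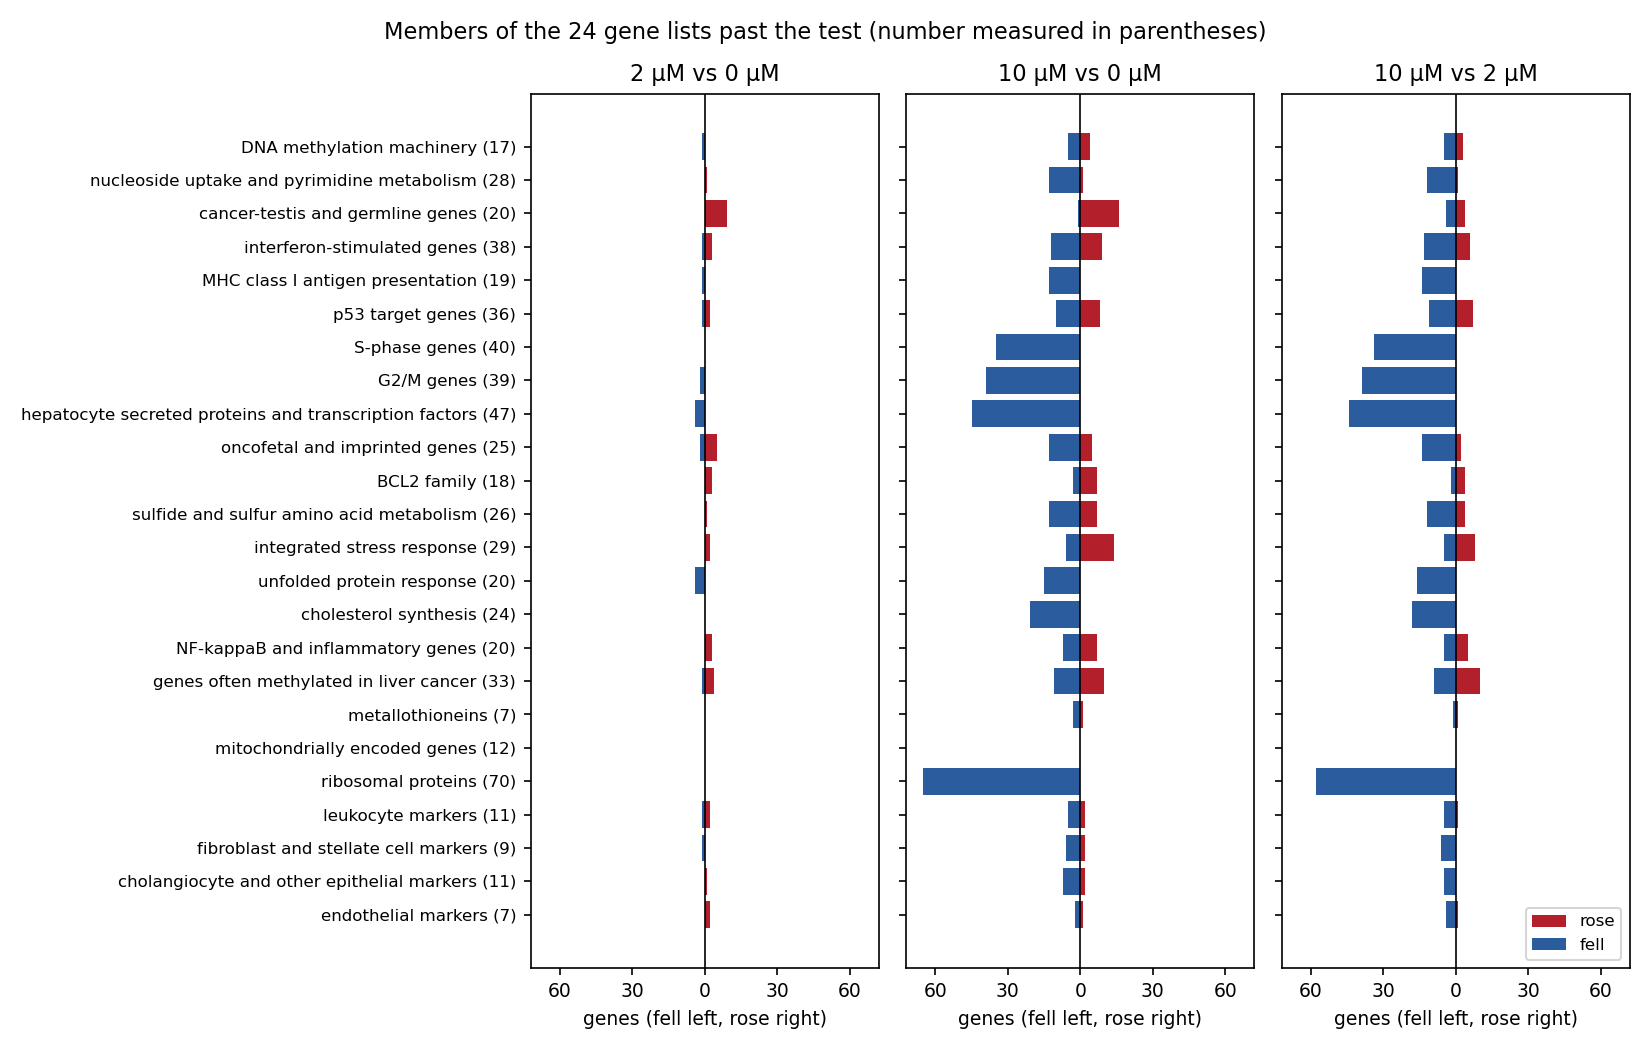
Members of each of 24 gene lists that fell (bars to the left) or rose (bars to the right) in edgeR, as numbers of genes on the horizontal axis, with 1 row per list and 1 panel per comparison. At 10 against 0 µM all 39 G2/M genes and 45 of 47 liver genes fell. In the cancer-testis list 16 of 20 measured genes rose, or 21 of 51 without the count filter, which favours rises. Under total-count scaling 50 rather than 65 ribosomal protein genes fell.

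The remaining 12 lists did not pass at 10 µM although most held members that did. Of 18 BCL2 family genes 7 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0597). Without 0 µM replicate 1, 2 µM replicate 3, or 10 µM replicates 2 or 3 the BCL2 family list was called higher (0.0446, 0.0301, 0.0469 and 0.0426), as it was without the count filter (0.0111). The death-promoting member PMAIP1 rose from 1.31 to 27.9 CPM (log2 4.40, SE 0.586, adjusted p = 5.65e-05), and both the survival factor MCL1 (1.43) and its opponent BAK1 (1.54) rose. Of 26 sulfide and sulfur amino acid genes 13 fell and 7 rose, also adjusted over the list alone (adjusted p = 0.344). Those that rose included both subunits of the glutathione-making ligase, GCLC (1.75) and GCLM (1.93), while MAT1A, the liver form of methionine adenosyltransferase, fell by 3.70. Of 29 integrated stress response genes 14 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.0597), the stress-induced SESN2 rising by 3.35. That list was called higher without 0 µM replicate 3 (0.00294), 2 µM replicates 1 or 3 (0.0493 and 0.0425), or 10 µM replicates 1 or 3 (0.0448 and 0.0223), and without the count filter (0.0111). Of 38 interferon-stimulated genes 9 rose and 12 fell, also adjusted over the list alone (adjusted p = 0.99; median -0.0173 and mean -0.0107 with the test leaning up, and a median of 0.234 under total counts). Of 36 p53 targets 8 rose and 10 fell, or 9 and 11 adjusted over the list alone (adjusted p = 0.686). Of 33 genes often methylated in liver cancer 10 rose and 11 fell, or 11 each adjusted over the list alone (adjusted p = 0.686; median 0.0293, mean -0.356, test up), the Ras-binding tumour suppressor RASSF1 rising by 2.06. Of 20 NF-kappaB and inflammatory genes 7 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.815; median 0.0135, mean -0.0389, test up). Of 7 metallothioneins 1 rose and 3 fell, also adjusted over the list alone (0.679). None of the 12 mitochondrially encoded genes passed in edgeR, with 1 lower at an unadjusted p under 0.05 and 1 in DESeq2 (0.686). Of 11 leukocyte markers 2 rose and 5 fell (0.0699), and the list was called lower without 0 µM replicates 1 or 2 (0.0446 and 0.0325) or 10 µM replicates 1 or 3 (0.0448 and 0.042). Of 7 endothelial markers 1 rose and 2 fell (0.809; median -0.882, mean -0.347, test up). Both counts were the same adjusted over the list alone. ESAM, the endothelial marker that rose, reached 331 ± 54.3 CPM (log2 4.72, SE 0.388, adjusted p = 1.37e-06).

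DNA methyltransferases and their partners, the targets of the drug, were asked about separately. DNMT3B, which sets new methylation (ENSG00000088305.19, chr20:32762385-32809356), fell at 10 µM from 29.7 ± 7.74 to 10.4 ± 1.07 CPM (log2 -1.51, SE 0.225, adjusted p = 0.000134). UHRF1, which guides DNMT1 to replicated DNA (ENSG00000276043.5, chr19:4903080-4962154), fell from 164 ± 94.7 to 24.3 CPM (log2 -2.76, SE 0.412, adjusted p = 0.00014). DNMT1, the maintenance enzyme (ENSG00000130816.17, chr19:10133346-10194953), stood at 120 ± 22.9, 113 ± 14.2 and 87.0 ± 1.29 CPM and did not pass at 10 µM (adjusted p = 0.0525), but did without 0 µM replicate 3 (0.00822). DNMT3A (ENSG00000119772.19, chr2:25227874-25342590) fell from 127 ± 22.6 CPM at 2 µM to 63.7 ± 6.27 CPM at 10 µM (adjusted p = 0.00133). Against 91.4 ± 13.2 CPM at 0 µM its fall at 10 µM (log2 -0.52, SE 0.19, adjusted p = 0.0368) was lost without 0 µM replicates 1 or 2, 2 µM replicate 1 or any 10 µM library (0.0519 to 0.147), under total counts (0.299) and without a filter (0.0778). None of these enzymes nor UHRF1 passed at 2 µM (adjusted p = 0.191 to 0.85), although UHRF1 did without 0 µM replicate 3 (0.0181). The list of 17 genes had 4 that rose and 5 that fell at 10 µM, or 4 and 6 adjusted over the list alone (adjusted p = 0.686), and at 2 µM 1 that fell, over the list alone too (adjusted p = 0.233, or 0.0302 without 0 µM replicate 3). The latter was the demethylase TET1 (adjusted p = 0.0401), a call lost without any 1 of the libraries other than 2 µM replicate 3 (up to 0.155, without 2 µM replicate 1). The methyl-CpG binder MBD1 rose at 10 µM by 1.63, and TET1 fell by 2.71.

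The comparison of 10 with 2 µM asks what the higher dose added. MMP1, a collagenase, rose and a further loss of liver and cell-division RNA set the doses apart. Of 18999 genes 3193 rose and 4112 fell. MMP1 (ENSG00000196611.6, chr11:102789919-102798160) went from 0.730 to 84.8 CPM (log2 6.85, SE 0.932, adjusted p = 0.000115). Haptoglobin HP (ENSG00000257017.10, chr16:72054505-72061055), which shares reads with its neighbour HPR, went from 368 to 0.415 CPM (log2 -9.76, SE 0.685, adjusted p = 8.14e-07). C8A of the complement attack complex fell by 9.70 (SE 0.492, adjusted p = 2.22e-07). H19 fell by 6.03 (SE 0.481, adjusted p = 1.87e-06) and DKK1 rose by 2.29 (SE 0.35, adjusted p = 0.000276), each against its change at 2 µM. All 39 G2/M genes (adjusted p = 3.62e-58; 0.131 with an estimated correlation), 44 of 47 liver genes (adjusted p = 1.3e-47; 0.131 with an estimated correlation) and 34 of 40 S-phase genes fell, or 35 adjusted over the list alone (adjusted p = 1.69e-12; adjusted p = 0.398 with an estimated correlation). Of 70 ribosomal proteins 58 fell, or 64 adjusted over the list alone (adjusted p = 1.03e-09; adjusted p = 0.5 with an estimated correlation). Of 20 unfolded protein response genes 16 fell (adjusted p = 7.15e-07; adjusted p = 0.274 with an estimated correlation), and of 24 cholesterol genes 18, or 20 adjusted over the list alone (adjusted p = 9.78e-05; adjusted p = 0.519 with an estimated correlation). Of 19 MHC class I presentation genes 14 fell (1 rose adjusted over the list alone; adjusted p = 5.88e-05; adjusted p = 0.274 with an estimated correlation), and of 25 oncofetal and imprinted genes 14 fell and 2 rose (adjusted p = 8.26e-05; adjusted p = 0.274 with an estimated correlation). Nucleoside genes had 12 falls and 1 rise (adjusted p = 0.00905; adjusted p = 0.274 with an estimated correlation). Fibroblast markers had 6 falls of 9 (adjusted p = 0.00397; adjusted p = 0.131 with an estimated correlation), leukocyte markers 5 falls and 1 rise of 11, or 6 and 1 adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.307 with an estimated correlation and 0.0792 without the count filter). Cholangiocyte markers had 5 falls of 11 (adjusted p = 0.0186; adjusted p = 0.274 with an estimated correlation), a call lost without 10 µM replicate 2 (0.0592). Where no other count is given, the one adjusted over the list alone was the same.

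In 12 lists no difference between 10 and 2 µM passed. Cancer-testis genes had 4 rises and 4 falls (adjusted p = 0.483), with TDRD12 at -1.46 and TEX14 at 2.55. Interferon genes had 6 rises and 13 falls, or 7 and 14 adjusted over the list alone (0.351), and p53 targets 7 and 11, or 7 and 12 (0.766). BCL2 family genes had 4 rises and 2 falls (0.184), sulfide genes 4 and 12 (0.225, or 0.03 without the count filter) and integrated stress response genes 8 and 5 (0.45). NF-kappaB genes had 5 and 5 (0.989; median -0.0984 and mean -0.21 with the test up, and a median of 0.00626 under total counts). Genes often methylated in liver cancer had 10 and 9, or 10 and 11 adjusted over the list alone (0.989; median -0.584, mean -0.492, test up). DNA methylation genes had 3 and 5, or 4 and 5 (0.989; median 0.215, mean -0.153, test up). Metallothioneins had 1 and 1, with the fall lost over the list alone (0.753; median 0.298, mean -0.0977, test up). Mitochondrially encoded genes had none in edgeR, at an unadjusted p under 0.05 or in DESeq2 (0.989; median -0.178, mean -0.249, test up), and endothelial markers 1 and 4 (0.351).

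Genes silent without drug were counted because methylation can hold genes silent. Of 63187 deposited genes 43129 had under 0.1 CPM at 0 µM, 14766 of them with a count in some library. The count filter passed 742, mostly where a drug group was high, so rises were favoured and falls all but ruled out, and the shares of the 742 have no meaning for silent genes as a whole. Of these 742, 191 rose at 2 µM, 124 of them protein coding, and 530 rose at 10 µM, 308 of them protein coding. Without the filter, an alternative added after the data were seen, 343 rose and none fell at 2 µM, and 853 rose and 28 fell at 10 µM. Dropping the filter does not free the direction, since genes chosen for under 0.1 CPM at 0 µM have little room to fall against those libraries. The excess of rises is thus not evidence by itself that silenced genes came on. At 2 µM the count was 107 without 0 µM replicate 1, 124 without 0 µM replicate 2, 98 without 2 µM replicate 1 and 81 without 2 µM replicate 2. With the filter the 1 silent gene that fell at 10 µM was the histone gene H3C8, which shares sequence with its copies and was named after its value was seen. The retinol dehydrogenase DHRS9, at 0.0770 CPM without drug, reached 45.9 CPM at 10 µM (log2 9.09, SE 0.788, adjusted p = 2.06e-06).

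Most genes that changed at 2 µM changed the same way at 10 µM, with 483 rising at both doses and 185 falling at both, such as ATL3, CDKN2A and AFP. Independent lists of these sizes would share 141 and 50.7. In 20 simulations of unchanged groups and their shared controls, all drawn around the control means, the covariance of the log2 changes at the 2 doses was 0.125 (0.12 to 0.13), where the observed one was 1.05, a difference of 0.922. Their correlation across genes was 0.515 (0.503 to 0.533) in the simulations from the shared controls alone, and 0.594 as observed. The simulations held at most 3 calls per dose and 1 shared gene, so their overlap of calls says nothing about 483 and 185. The draw of the controls was added after the data were seen. With separate controls, 1 of the 3 for one dose and the other 2 for the other in each of the 6 ways, an alternative added after the data were seen, the covariance was 0.795 to 1.2 and the correlation 0.35 to 0.525. These fits, in which 1 dose has a single control library, shared 30 to 462 rises and 8 to 464 falls, where independent lists would share 8.57 to 173 and 2.16 to 211. Part of the 483 and 185 may still rest on the shared controls. The rising overlap was 251, 317, 216, 200 and 744 without 0 µM replicates 1 and 2 and 2 µM replicates 1, 2 and 3. The falling overlap was 86 and 415 without 0 µM replicates 1 and 3, 26, 29 and 395 without 2 µM replicates 1 to 3, and 106 and 99 without 10 µM replicates 1 and 3. Another 18 genes rose at one dose and fell at the other; with separate controls they were 0, 2 and 171 with 0 µM replicates 1, 2 and 3 alone for 2 µM, and 6, 2 and 95 with them alone for 10 µM.

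The chromatin comparisons ask where accessibility changed. At 2 µM 9044 of 58372 peaks rose and 4260 fell, at 10 µM 17436 and 16125, and between those doses 16069 and 16097. Of the consensus peaks 20501 are named for 0 µM, 18054 for 2 µM and 25066 for 10 µM. If a name gives the dose at which the peak was found, peaks open at only 1 dose entered the set, which favours large changes both ways. Counts, shares and correlations across peaks hold for this set alone. TMM centres the changes, so the balance of rises and falls does not show whether chromatin opened or closed overall. Rises and falls at 10 µM were 16596 and 16902 with RLE scaling and 16024 and 17452 under total counts, at 2 µM 8357 and 5451, and 9423 and 4037, and between the doses 16084 and 16103, and 13625 and 17769. The 9044 became 5324 without 0 µM replicate 2, and the 4260 became 2569 and 2405 without 2 µM replicates 2 and 3 and 7051 and 7029 without 10 µM replicates 1 and 2. Of 2514 peaks in 3′ untranslated regions 26.0% rose and 4.73% fell at 2 µM, as did 21.7% and 8.75% of 20813 intron peaks, 18.8% and 5.81% of 3962 exon peaks, 11.9% and 2.51% of 916 peaks in 5′ untranslated regions, 7.04% and 5.01% of 19763 promoter peaks, and 15.6% and 10.4% of 10283 distal intergenic peaks. At 10 µM 22.8% of the peaks in 3′ untranslated regions rose and 39.9% fell, 36.2% and 34.9% of those in introns, and 20.5% and 14.9% of those at promoters. These shares were not tested. The peak in exon 3 of COLGALT1, a collagen-modifying enzyme (chr19:17560102-17560602), rose at 2 µM from 0.954 to 14.0 CPM (log2 4.01, SE 0.348, adjusted p = 2.25e-09) and stood at 12.8 CPM at 10 µM. A peak in an intron of the polycomb gene PCGF3 (chr4:740849-741349) rose by 3.57 (SE 0.259, adjusted p = 9.88e-11), and one in the 3′ untranslated region of PDCD6 (chr5:310841-311341) by 3.50 (SE 0.268, adjusted p = 2.99e-10). An intronic peak nearest WIPI1 (chr17:68482533-68483033) fell from 12.7 to 2.08 CPM (log2 -2.66, SE 0.295, adjusted p = 9.42e-08). At 10 µM a peak in an intron of MED27 (chr9:131986580-131987080) rose from 0.144 CPM, with 1, 0 and 1 counts, to 11.3 CPM, with 108 and 37 counts (adjusted p = 5.25e-12). An intergenic peak (chr5:80607757-80608257) fell from 9.41 CPM at 0 µM to 0.176 CPM at 10 µM, with 1 and 1 counts (adjusted p = 4.72e-11). With so few counts in a group the fold of either peak is uncertain.

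Promoter accessibility and RNA were set side by side to ask whether genes that rose had promoters that opened. Among 11582 genes with both measured, 126 of 313 that rose at 2 µM had a promoter peak that rose (40.3% against 11.8% of other genes; odds ratio 5.02, 95% interval 3.94 to 6.37, two-sided Fisher's exact test, adjusted p = 8.32e-36). At 10 µM it was 1339 of 2990 (44.8% against 29.3%; odds ratio 1.96, 1.79 to 2.13, adjusted p = 4.28e-52). Of genes that fell at 10 µM, 1252 of 3355 had a promoter peak that fell (37.3% against 15%; odds ratio 3.38, 3.08 to 3.71, adjusted p = 8.32e-145). At 2 µM 28 of 168 falling genes had one (16.7% against 8.25%; odds ratio 2.22, adjusted p = 0.000375), a result lost without 2 µM replicate 1 (odds ratio 2.45, adjusted p = 0.106) or replicate 2 (1.43, adjusted p = 0.475), and with an odds ratio of 3.59 without 2 µM replicate 3. Across genes, which are not independent replicates, Spearman's rho of the promoter and RNA changes was 0.16 at 2 µM and 0.325 at 10 µM. HSD17B1, which makes estradiol, rose at 2 µM by a log2 of 4.40 (SE 0.377, adjusted p = 6.88e-05) with a promoter peak (chr17:42553227-42553727) up by 1.54 (SE 0.164, adjusted p = 4.95e-08). SERPINA10, a plasma protease inhibitor, fell at 10 µM by 4.57 (SE 0.207, adjusted p = 6.33e-08) with a promoter peak (chr14:94292889-94293389) that fell by 1.54 (SE 0.159, adjusted p = 4.47e-10).

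**Figure D4:**
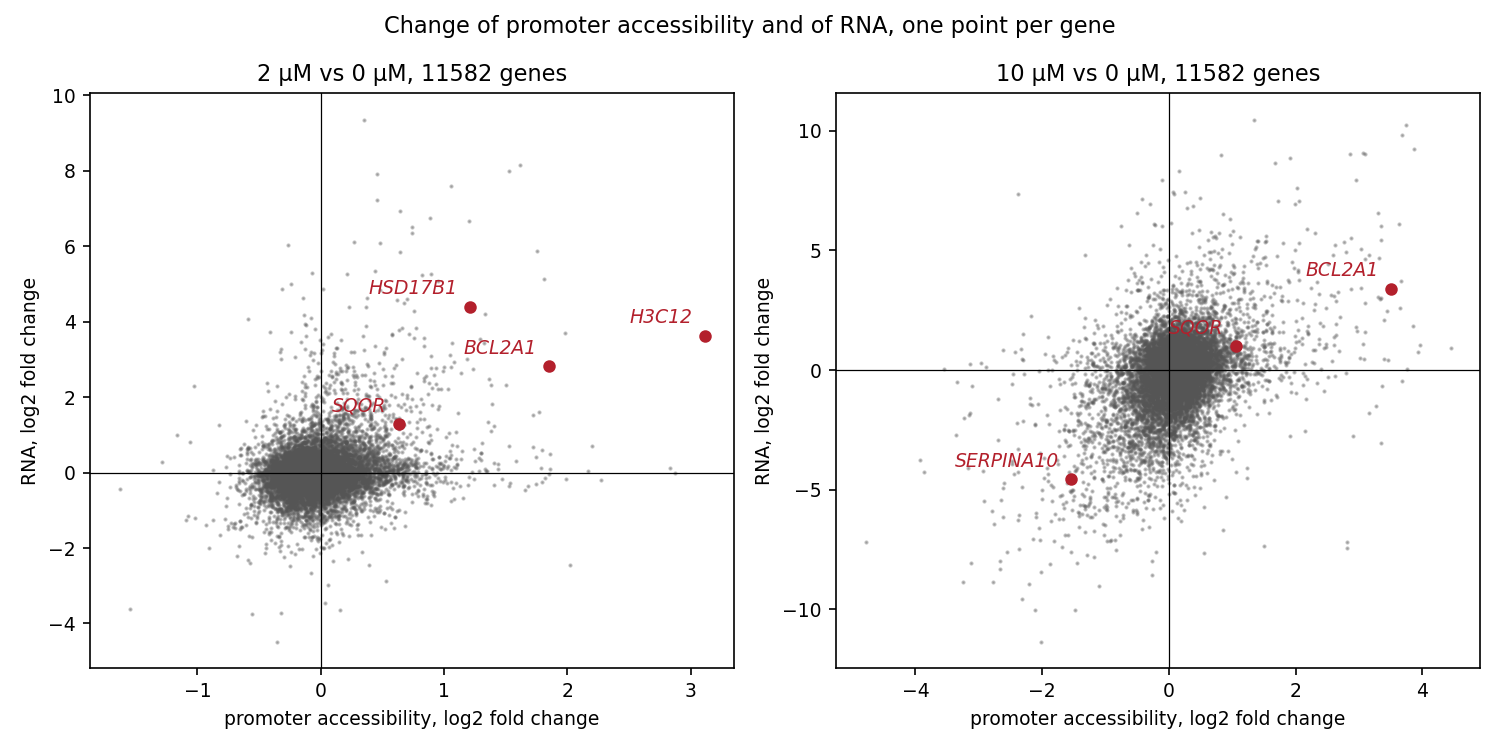
Log2 change of promoter accessibility (horizontal axis, mean over a gene's peaks within 1000 bp of a transcription start) against log2 change of RNA (vertical axis) for 11582 genes, 1 point per gene, at 2 µM and at 10 µM against 0 µM. BCL2A1 and SQOR lie in the upper right of both panels, and Spearman's rho was 0.16 and 0.325.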

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

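The tests of depth, of other cell types and of chromosome shares, those of an untreated library and of swapped labels, and the slopes on gene sets of equal size were chosen after the results they bear on were seen; the test of a shift shared by the libraries numbered 3 was chosen before.

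A total of 18 genes rose at one dose and fell at the other, each against 0 µM, with the doses also differing from each other in edgeR; with separate controls for each dose the genes of opposite direction numbered 0 to 171. CD14, a co-receptor for bacterial lipid and a marker of monocytes that hepatocytes also make, was the one among them that the naming rule gave. It rose from 2.90 ± 1.01 to 13.3 ± 6.01 CPM at 2 µM (adjusted p = 0.0138) and fell to 0.196 ± 0.137 CPM at 10 µM (log2 -3.84). Between the doses its log2 change was -6.04 (SE 0.542, adjusted p = 4.53e-06). Among the others, singled out after their values were seen, the histone gene H3C12 changed by 3.63 at 2 µM and -2.45 at 10 µM, and the liver microRNA host MIR122HG by 5.08 and -2.90. No explanation was tested for these genes.

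The ATAC libraries at 10 µM lay far from those at 0 µM, with a median correlation of 0.338 across peaks. A difference in depth is argued against, because with every library thinned to 2896671 reads the median correlation was 0.341, while the 0 µM libraries still correlated at 0.937 and the 10 µM pair at 0.917. Markers in the RNA libraries, which are separate from the ATAC ones, argue against leukocytes, fibroblasts or endothelial cells as most of the 10 µM cells. The highest of the median member levels of these lists at 10 µM was 0.141 CPM. Single members stood high, such as ESAM (331 CPM), TAGLN (194 CPM, 45.8 CPM in control) and FN1 (1655 CPM, lower than in control). Members without counts at any dose, such as PTPRC, FAP and CLDN5, hold the medians low, but their absence also argues against a sizeable minority of such cells. At 10 against 0 µM 2 measured leukocyte markers rose and 5 fell. For fibroblast and stellate cell markers the counts were 2 and 6, and for endothelial markers 1 and 2. A small minority of such cells stays open. Other epithelial cells stay open, since the line itself holds their markers (a median of 92.4 CPM over the measured members at 0 µM and 20.7 CPM at 10 µM). Loss of the line's chromosome gains is argued against, because the share of reads of no chromosome differed by more than 0.0986 in log2. An effect of the drug itself, the biological explanation the design gives, stays open and may account for the distance of 10 from 0 µM.

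RNA of 2 µM replicate 3 had moved less from control than that of the other 2 µM replicates. An untreated library under a 2 µM label is argued against, since it showed a median share of 0.385 of the rise in 137 genes all but absent from control, and 94.2% of them had a count in it. A swap of labels between 0 and 2 µM is argued against by correlations across all tested genes. Every 0 µM library correlated more with the other 0 µM libraries (0.965 to 0.981) than with 2 µM replicates 1 and 2 (0.94 to 0.963). Correlations do not set 2 µM replicate 3 itself apart from control. It stood at 0.9665, 0.9697 and 0.9709 with 0 µM replicates 1 to 3, and at 0.9691 and 0.9735 with 2 µM replicates 1 and 2. For 0 µM replicate 3 that 0.9709 was above its values with 0 µM replicates 1 and 2 (0.9653 and 0.9665). The highest slope of a 0 µM library toward the 2 µM group was 0.0571. That slope decides nothing, since its genes were called with all 0 µM libraries, which favours genes in which these agree. A shift shared by the libraries numbered 3 could explain the smaller move only if 0 µM replicate 3 were its proper baseline, and against that baseline the slope was still 0.457 over 2170 genes called without the libraries numbered 3. Replicates 1 and 2 gave 0.945 and 1, but over only 80 and 62 genes; over the 62 genes of smallest p without each number the slopes of replicates 1 to 3 were 0.971, 1 and 0.572, and over 2170 genes 0.97, 0.826 and 0.457. A lower effective dose, or a mixture of treated and untreated cells, may account for the values and was not tested.

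For 4 comparisons the real split was set beside the other splits of the same 6 libraries into groups of 3. In each of them 1 of 10 splits, the real one, gave the most calls in a fit of those 6 libraries, over the genes or peaks that passed the filter on all libraries: 428 genes for RNA at 2 against 0 µM, 9115 at 10 against 0 µM and 8491 at 10 against 2 µM, and 16120 peaks for ATAC at 2 against 0 µM, with 0 calls as the highest of the other splits in each. With 10 splits no share under 0.05 can be reached.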

How the results depend on the processing

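Tests chosen after the data were seen were those without both libraries numbered 3 of 0 and 2 µM, the block over 0 and 2 µM alone, the block with exchanged 10 µM numbers, leaving out libraries for the silent genes, overlap and promoter results, lists and silent genes without a filter, and the overlap with separate controls. Unless a construction is named, the cause was not tested.

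Genes called at 10 against 0 µM and at 10 against 2 µM, and peaks called at 10 µM, kept within 1.5 times their counts under every alternative except the further threshold of 1 on the log2 change, which by construction calls fewer. It left 2776 rises at 10 against 0 µM, 1654 at 10 against 2 µM, 122 falls at 2 µM and 110 shared falls; for peaks it left 4603 rises and 513 falls at 2 µM, 10844 and 9885 at 10 µM, and 7700 and 9687 between the doses. The 611 rises and 202 falls of RNA at 2 µM also moved: 94 falls under total counts, 982 and 539 in DESeq2, 1030 and 673 without a filter, and 352 and 57 with only those groups in the fit, which has fewer libraries and filters genes on them alone. Without both libraries numbered 3 they were 1382 and 788, with 1141 rises and 723 falls shared between doses and 333 and 756 silent genes rising. Peaks at 2 µM gave 5825 rises in DESeq2 and 6919 falls with only the groups compared. With separate controls the 483 shared rises became 70, 30 and 331 with 0 µM replicates 1, 2 and 3 alone for 2 µM and 200, 241 and 462 with them alone for 10 µM, and the 185 shared falls 12, 8 and 464, and 77, 135 and 292; a dose with a single control library leaves less to test with. Silent genes with 0 counts in control gave 54 rises at 2 µM and 99 at 10 µM, from the 106 of 33788 that passed the filter, which favours genes high with drug. Without a filter 343 and 853 silent genes rose, and genes chosen as silent at 0 µM have little room to fall.

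With the replicate number as a block over 0 and 2 µM, 399 genes rose and 314 fell at 2 µM; with the block over all doses 598 and 302, and with exchanged numbers 701 and 391. The blocks changed no list call beyond those given with the results. Other comparisons share only a number: their same-number correlations were 0.0114, -0.0263 and -0.0652 for RNA at 10 against 0 µM, 0.0559, -0.0526 and -0.0463 at 10 against 2 µM, 0.134, -0.0124 and -0.0539 for ATAC at 2 against 0 µM, -0.121 and -0.168 at 10 against 0 µM, and -0.224 and 0.01 at 10 against 2 µM, and the block kept their counts within 1.5 times.

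Leaving out 1 library at a time gave 244 to 947 rises and 29 to 462 falls in RNA at 2 µM, 5324 to 9120 rises and 2405 to 7051 falls of peaks at 2 µM, 200 to 744 shared rises and 26 to 415 shared falls, and 81 to 268 silent genes rising at 2 µM. The odds ratio of falling genes and promoters at 2 µM lay between 1.43 and 3.59. Lists called higher numbered 2 to 6 at 2 µM and 1 to 3 at 10 µM. With an estimated correlation 0 lists were called in any comparison, where 1, 5 and 3 had an unadjusted p under 0.05 at 2 against 0, 10 against 0 and 10 against 2 µM. Fry, which asks whether a list moves one way and not whether it moves more than other genes, called 1 list higher and 0 lower at 2 against 0 µM, 2 higher and 13 lower at 10 against 0 µM, and 0 higher and 15 lower at 10 against 2 µM. Without a filter camera called 6 lists higher and 6 lower at 2 µM, 3 and 10 at 10 against 0 µM, and 0 and 12 at 10 against 2 µM. Without both libraries numbered 3 camera called 3 lists higher at 10 µM.

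Every tested result that changed direction was one that did not pass in the original fit. List medians carry no test, and under total counts that of the ribosomal proteins, called lower at 2 µM, turned from -0.113 to 0.0439; among uncalled lists the medians of DNA methylation, nucleoside, sulfide and liver cancer methylation genes at 2 µM, of DNA methylation, interferon and leukocyte genes at 10 against 0 µM and of NF-kappaB genes at 10 against 2 µM turned as well. For DNMT1 at 2 µM the log2 change was 0.064 under total counts and -0.24 to 0.048 without single libraries. Mitochondrial genes changed sign without 0 or 2 µM replicate 3, the libraries with the most mitochondrial mRNA. At 2 µM MT-ND4 ranged from -1.29 to 0.47, MT-CO2 from -1.47 to 0.31 and MT-ATP6 from -1.70 to 0.45. At 10 against 0 µM MT-ND4 ranged from -1.43 to 0.18 and MT-CO2 from -1.29 to 0.16, and without both replicates 3 they were 0.18 and 0.16. At 10 against 2 µM MT-ND4 ranged from -0.56 to 0.28 and MT-CO3 from -0.55 to 0.16, and without both replicates 3 they were 0.28 and 0.15. The SQOR intron peak at chr15:45635245-45635745 ranged from -0.051 to 0.018 between 2 and 10 µM.

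Lists changed direction as follows, each given as adjusted p. With fry they were interferon genes at 10 against 0 µM (0.466) and, at 10 against 2 µM, DNA methylation (0.532), NF-kappaB (0.733), liver cancer methylation (0.443) and mitochondrial genes (0.824). With the block over all doses they were oncofetal (0.774) and sulfide genes (0.996) at 2 µM, interferon (0.934) and NF-kappaB genes (0.999) at 10 against 0 µM and NF-kappaB genes at 10 against 2 µM (0.898); with the block over 0 and 2 µM, oncofetal and NF-kappaB genes at 2 µM (0.799 each). Without a filter they were leukocyte (0.904) and fibroblast markers (0.923) at 2 µM, interferon genes (0.731) and endothelial markers (0.934) at 10 against 0 µM and, at 10 against 2 µM, DNA methylation (0.899), NF-kappaB (0.829), liver cancer methylation (0.824) and mitochondrial genes (0.854). Without both replicates 3 they were oncofetal genes at 2 µM (0.951), mitochondrial genes at 10 against 0 µM (0.496) and, at 10 against 2 µM, DNA methylation and NF-kappaB genes (0.767 each) and liver cancer methylation (0.895). Without single libraries the ranges at 2 µM were 0.404 to 0.935 for oncofetal, 0.713 to 0.993 for sulfide, 0.0302 to 0.974 for NF-kappaB, 3.52e-13 to 0.974 for S-phase and 0.00257 to 0.775 for mitochondrial genes. At 10 against 0 µM they were 0.528 to 0.998 for NF-kappaB, 0.55 to 0.998 for endothelial, 0.827 to 0.998 for interferon and 0.188 to 0.721 for mitochondrial genes. At 10 against 2 µM they were 0.82 to 0.999 for DNA methylation, 0.866 to 0.999 for NF-kappaB and for liver cancer methylation, and 0.349 to 0.999 for mitochondrial genes.

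Of 361 values of named genes, 361 kept direction and side of the threshold with RLE scaling, 341 with total counts, 341 in DESeq2, 329 without a filter, 351 with the block over all doses and 328 without both replicates 3. Of 3249 values without single libraries 3027 did, 174 ended a call, 39 gave one and 9 changed sign. Of 54 values of named peaks, 52 or more kept theirs under each alternative but the threshold of 1, which kept 50. Small RNA changes were often missed in simulation: of 2-fold changes 21% were recovered at 2 µM and of 4-fold changes 62%. That simulation changed fewer genes than the real comparison called, which makes the adjusted p stricter, so the real share missed is not known.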

Other observations

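All tests in this part, of 5 further gene lists, were chosen before their results were seen. The actin, NRF2 and heat shock lists were chosen because single members stood out at 10 µM, and these members were left out; the histone list followed from the loss of replication genes, and the zinc finger list from the drug's action.

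Replication-dependent histone genes may fall with the loss of replication genes at 10 µM. Of 60 measured, 52 fell and 1 rose, with a median log2 of -4.25 (camera p = 8.96e-25; adjusted p = 0.427 with an estimated correlation). At 2 µM 7 of them rose and none fell in edgeR, while the median was -0.806 and camera pointed down (p = 0.0543, adjusted p = 0.0905; adjusted p = 0.727 with an estimated correlation). Histone genes share sequence, so the share of reads of each is uncertain.

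Zinc finger genes of chromosome 19, many of which silence transposable elements, may rise where DNA methyltransferases are inhibited. At 10 µM 105 of 213 rose and 13 fell, with a median log2 of 0.686 (camera p = 3.51e-08; adjusted p = 0.427 with an estimated correlation). At 2 µM 4 rose, with a median of 0.157 (adjusted p = 0.0272; adjusted p = 0.727 with an estimated correlation).

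The actin genes ACTG1 and ACTB and the filamin FLNA stood high at 10 µM. The rest of a list of actin cytoskeleton genes and targets of SRF and YAP was therefore predicted to be higher than at 0 µM. Of 31 genes 13 rose and 5 fell (camera p = 0.00431; adjusted p = 0.427 with an estimated correlation).

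TXNRD1 and SQSTM1, both targets of the oxidative stress factor NRF2, stood high at 10 µM, but the rest of the NRF2 targets did not rise as a set against 0 µM: 7 of 28 rose and 15 fell, with the test pointing down (camera p = 0.189, adjusted p = 0.189; adjusted p = 0.511 with an estimated correlation). At 10 against 2 µM 9 rose and 6 fell, with a median of -0.0184 and the test pointing up (camera p = 0.063, adjusted p = 0.0788; adjusted p = 0.466 with an estimated correlation). At 2 µM 6 of the 28 fell, with a median of -0.429 (adjusted p = 1.5e-10; adjusted p = 0.066 with an estimated correlation).

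HSPA8 stood high at 10 µM, and whether the other heat shock genes rose as a set remains open. Of 22 others 9 rose and 4 fell, and camera pointed up with p = 0.06 (adjusted p = 0.075; adjusted p = 0.511 with an estimated correlation). The bound set beforehand against the idea was any p of at least 0.05, but a value just past that threshold in the predicted direction excludes nothing, so that bound was wrong.

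The share of albumin RNA was 1.65%, 1.28% and 2.16% of counts in the 0 µM libraries, 0.525%, 0.613% and 1.06% at 2 µM, and 0.0661%, 0.131% and 0.0723% at 10 µM. LYZ, which encodes the lysozyme of leukocytes, stood at 2747 CPM at 0 µM and 73.4 CPM at 10 µM in this liver line, so the leukocyte list holds a gene that the line itself expresses strongly. The fibroblast gene FN1 is also made by liver cells.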
